A study of Homo sapiens with 8 samples.

How the data were processed

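RNA near the peroxidase APEX2 was captured in HEK293T cells and sequenced. APEX2 sat in the nucleus (NLS) or at the outer mitochondrial membrane (OMM). Each compartment had 2 labelled and 2 unlabelled control libraries, 8 in all. The NLS libraries, titled ribominus, were made with a SMARTer stranded total RNA kit and the OMM libraries, titled trizol, with a TruSeq stranded mRNA kit, which selects poly(A) RNA, per the labels. The series description gives release of captured RNA with Proteinase K for NLS and with TRIzol for OMM, whereas the sample labels name an RNeasy kit for all, so the release step is not settled. The compartment coincides with the kit and the selection of RNA. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

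The authors deposited read counts per gene, made with HTSeq after alignment with STAR, per the submitters' processing notes and the file headers. Those notes also name Trimmomatic, SAMtools, bedtools and DESeq2 and the builds GRCh38.p13 and hg38; their versions and the strand setting of the counting are not given in the sources used here. Genes that overlap or lie antisense to another gene, and copies such as pseudogenes, are therefore uncertain. The authors also deposited a log2 fold change of labelled over control per gene. They deposited a p-value per gene as well. DESeq2 run here on the deposited counts gave fold changes within 0.01 of theirs for 100% of genes in both compartments. Its adjusted p lay within 1% of theirs for 100% of NLS genes and 99.99% of OMM genes, so their p-value is an adjusted one. Values from that table are named as the authors' and carry no error of their own.

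A column was given to a group only where its name showed the compartment and the arm. The numbers in the column names differ from those in the sample titles: 1 and 3 in the NLS table, 3 and 4 for the OMM controls, 2 and 3 for the labelled OMM libraries. Libraries are named by these numbers. The tables also held 4 count columns and 2 comparison columns whose names matched no sample, and these were not used beyond an early look at their totals and correlations. The count tables listed 60664 genes and no total or unassigned line. Of their identifiers, 58396 were found in GENCODE 29 (GRCh38), from which gene types and coordinates were taken. A symbol was shared by more than 1 identifier for 1287 genes.

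Total counts were 20746393 and 21096586 in the NLS controls, 9531568 and 8039176 in the labelled NLS libraries, 41660431 and 35165227 in the OMM controls, and 52421161 and 34705126 in the labelled OMM libraries. A floor of 3 counts corresponds to 0.142 to 0.373 CPM at NLS and 0.0572 to 0.0864 CPM at OMM. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. No 2 libraries of a group agreed within sampling noise, so each was counted as a replicate. The chi-square per degree of freedom was 26.7 for the NLS controls, 4.98 for the labelled NLS libraries, 184 for the OMM controls and 229 for the labelled OMM libraries.

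Counts were tested with edgeR 4.0.16 in R 4.3.3 by its robust quasi-likelihood F test. Libraries were scaled with TMM factors, which ran from 0.826 to 1.20 at NLS and from 0.936 to 1.05 at OMM. Genes were kept by filterByExpr with its minimum count of 10, the prior count was 0.125, and p-values were adjusted over all tested genes by the Benjamini-Hochberg method with a threshold of 0.05. All tests were two-sided. The NLS and OMM libraries were fitted apart. The difference between compartments was the interaction term of a joint fit of the 8 libraries. CPM values are scaled with the same TMM factors. Standard errors (SE) of log2 fold changes are the size of the fold change divided by the square root of F. A gene with a group at 0 counts has no fitted fold printed, and medians over groups of genes were also computed with such genes at a bound of 3 counts per library.

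The 29 gene lists, the designs, the named-gene rule and most alternatives were fixed before the data were examined. Lists with at least 5 measured members were tested with camera (limma 3.58.1), with a preset correlation of 0.01 between genes, and adjusted over lists. The ribosomal RNA gene list had too few measured members. Camera with an estimated correlation and the rotation test fry were alternatives. With an estimated correlation, camera rests on the few residual degrees of freedom left by 2 libraries per group. It then has little power, so a list that fails it is undecided. Fry asks whether members changed, without comparing them with other genes. Enrichment of a list among called genes was tested with Fisher's exact test over all tested genes.

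Named genes were chosen as follows. The 6 highest and 6 lowest log2 fold changes were taken among genes past the threshold with a mean log2 CPM of at least 4, with both labelled libraries on the same side of both controls, leaving out clone names and copies of small RNAs. Each list gave its member with the highest mean CPM and the 2 with the smallest p, of which a subset is named. The anchors were MALAT1, NEAT1, RN7SK, GAPDH, ACTB, HSPA5, ATP5F1B, MT-ND1 and MT-CO1. The difference between compartments gave its 5 highest and 5 lowest genes and the anchors.

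The alternatives were size factors in place of TMM, library size alone, no filter, a filter on a group mean of at least 10 counts, DESeq2 1.42.0, a test against a log2 fold change of 1, a replicate block, each library left out in turn, and the removal of mtDNA-encoded genes, ribosomal RNA genes and small RNAs. Removal of a loess trend (span 0.3) of transcript length or GC content, and a difference tested with separate spreads per compartment or with a block on the NLS replicate numbers, were added after the data were seen. A length was known for 98.1% of tested NLS genes and 99.1% of tested OMM genes. Length-matched comparisons drew 10000 random lists from 20 bins of transcript length and 5 of expression.

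The pipeline was tested on simulated counts drawn from the means and depths of these libraries. For each fold, 100 genes averaging at least 100 counts were changed. Recovery at lower counts was not tried. At NLS the pipeline recovered 85% of 2-fold and 98% of 4-fold changes, with 8 false calls among 20858 genes. At OMM it recovered 5% and 32%, with 4 false calls among 14438 genes. For the difference between compartments it recovered 0% and 14%, with 1 false call among 23178 genes. Of 20 unchanged lists of random genes per comparison, 0 were called. Simulated genes were drawn independently of each other, so this does not test lists of correlated genes. Few genes were changed, up and down alike, whereas at NLS 5999 rose and 5945 fell. The simulation therefore does not test TMM scaling where many genes change. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.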

Results

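HEK293T cells, a transformed line from human embryonic kidney, expressed APEX2, an engineered peroxidase that tags nearby RNA with biotin in living cells. The enzyme was directed to the nucleus (NLS) or to the outer mitochondrial membrane (OMM), and tagged RNA was pulled down on streptavidin beads and sequenced. Each compartment had 2 labelled libraries and 2 controls that were not labelled. The controls measure RNA recovered without labelling, not the RNA of whole cells, so each comparison asks which RNAs were recovered in larger or smaller shares when the enzyme at that site was active. The NLS controls held 20746393 and 21096586 counts and the labelled NLS libraries 9531568 and 8039176. The OMM controls held 41660431 and 35165227 counts and the labelled OMM libraries 52421161 and 34705126. Genes with at least 1 count numbered 24931 and 30715 in the NLS controls, 31638 and 31545 in the labelled NLS libraries, 16741 and 14356 in the OMM controls, and 14645 and 15692 in the labelled OMM libraries.

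Replicates differed more at OMM than at NLS. Across genes, which are not independent replicates, Pearson's correlation of log2 CPM was 0.968 between the NLS controls and 0.985 between the labelled NLS libraries, against 0.627 and 0.605 at OMM. Of genes averaging at least 100 counts, 533 of 12739 in the OMM controls and 593 of 12694 in the labelled OMM libraries had 0 counts in 1 of the 2 replicates, against 0 of 11976 and 0 of 11433 at NLS. The biological coefficient of variation was 0.166 at NLS and 0.958 at OMM.

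In the labelled NLS libraries, 20 of 29 long non-coding RNAs described as nuclear were higher, and lists of mitochondrial and cytoplasmic mRNAs were lower. As lists, 0 passed camera with an estimated correlation (smallest adjusted p = 0.138). KCNQ1OT1, an imprinted antisense RNA, rose from 59.2 ± 10.1 CPM in the controls to 1041 ± 64.9 CPM in the labelled libraries (SD, n = 2 each), a log2 fold change of 4.14 ± 0.15 (SE, adjusted p = 1.46e-05). NEAT1, the scaffold of paraspeckles, rose from 93.3 ± 9.39 to 1357 ± 118 CPM, a log2 fold change of 3.86 ± 0.13. MALAT1, a nuclear speckle RNA, rose from 1155 ± 38.6 to 5748 ± 720 CPM (log2 fold change 2.31 ± 0.13, adjusted p = 1.82e-05). MT-ATP6, the mtDNA-encoded subunit a of ATP synthase, fell from 4871 ± 982 to 483 ± 27.5 CPM (log2 fold change -3.33 ± 0.16, adjusted p = 1.82e-05).

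Of 20858 genes tested, 5999 rose and 5945 fell at an adjusted p under 0.05, and 4665 and 3226 of these changed at least 2-fold. The median log2 fold change of all genes was 0.14 under TMM scaling. With library size alone it moved to 0.66, and 9122 genes rose and 3351 fell. With the trend of transcript length removed 4616 rose and 7089 fell, and with the trend of GC content removed 4354 rose and 8158 fell. The length trend was fitted over all gene types. Length and fold change had a Spearman correlation of -0.223 over all genes but 0.210 among protein-coding genes. Its removal is therefore no correction among mRNAs at NLS, and it moved the median of the oxidative phosphorylation list from -1.40 to -1.85. Without labelled library 1 the counts were 3196 higher and 4660 lower, and without labelled library 3 they were 3077 and 4520. At an adjusted p under 0.05, 5630 genes rose and 5151 fell in the authors' deposited values, and 10528 genes were called there and here, all with the same sign.

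The largest rise among named genes was that of DANT2, a non-coding RNA on chromosome X from 115917271 to 115969089 (GRCh38, ENSG00000235244). It rose from 1.23 ± 0.764 to 37.1 ± 1.84 CPM, a log2 fold change of 4.90 ± 0.34 (adjusted p = 2.51e-05). KCNQ1OT1 (ENSG00000269821) spans 2608328 to 2699994 and NEAT1 (ENSG00000245532) 65422774 to 65445540, both on chromosome 11. PVT1 (ENSG00000249859), a non-coding RNA beside MYC, spans 127794533 to 128101253 on chromosome 8 and rose from 14.0 ± 1.51 to 147 ± 6.87 CPM (log2 fold change 3.39 ± 0.13). MIR924HG, a microRNA host on chromosome 18 from 39206924 to 39800318, rose by a log2 fold change of 3.36 ± 0.21. GPR135, an orphan receptor gene on chromosome 14 from 59429022 to 59465342, rose by 3.53 ± 0.20, but it overlaps L3HYPDH, so its reads are uncertain. Among the lowest, MT-ND3 (10059 to 10404 on the mitochondrial chromosome), a complex I subunit, fell from 445 ± 75.2 to 43.0 ± 1.06 CPM (log2 fold change -3.37 ± 0.14). MT-ATP8 and MT-ND2 fell with log2 fold changes of -3.21 ± 0.15 and -3.12 ± 0.16. MTATP6P1 on chromosome 1, a nuclear copy of mtDNA, and RPS2P46 on chromosome 17, a ribosomal protein pseudogene, gave -2.92 ± 0.12 and -3.32 ± 0.41, and reads of such copies are hard to tell from those of their source genes.

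**Figure D1:**
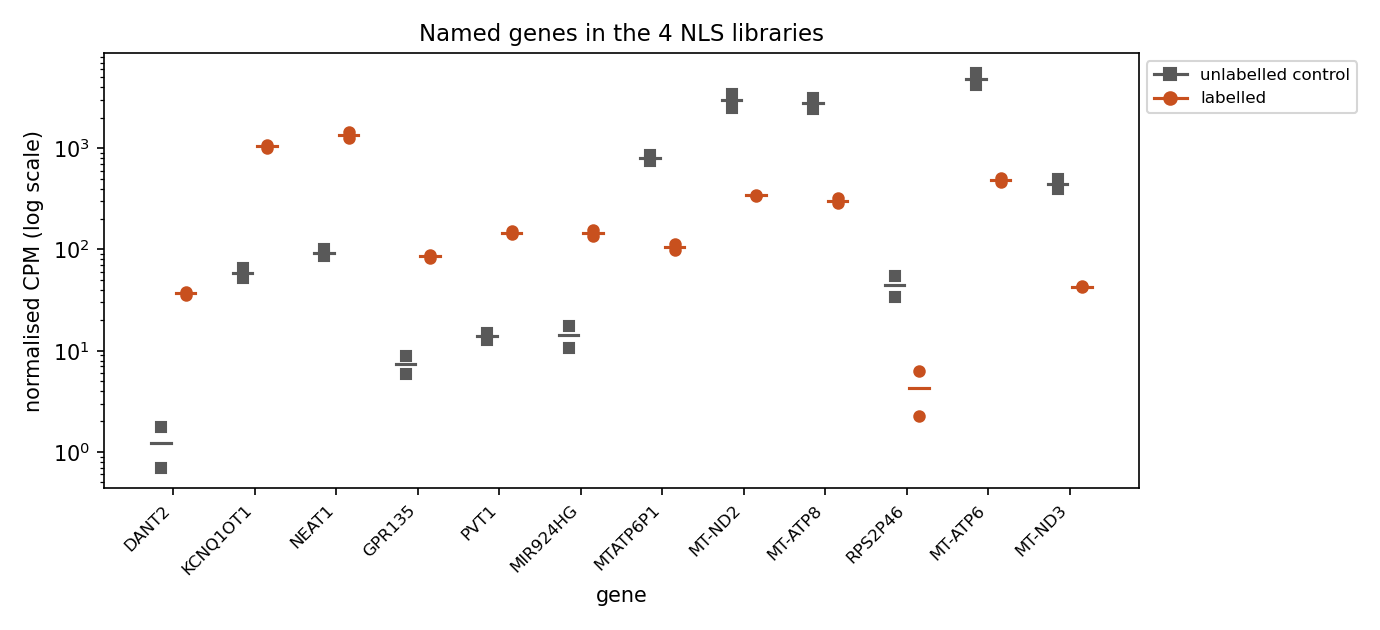
Normalised CPM (log axis) of the 6 highest and 6 lowest named genes in each of the 4 NLS libraries. Squares are unlabelled controls, circles labelled libraries, and lines the mean of 2 libraries; for each gene both labelled libraries lie on the same side of both controls, as for KCNQ1OT1 at 1041 against 59.2 CPM.

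Of 29 measured long non-coding RNAs described as nuclear, 20 rose and 2 fell, with a median log2 fold change of 1.81 (camera adjusted p = 7.34e-17; adjusted p = 0.186 with an estimated correlation). The count adjusted over the list alone was also 20 and 2. Non-coding hosts of small nucleolar RNAs (snoRNAs) rose in 14 of 29 genes and fell in 2, by a median of 0.57 (adjusted p = 0.00495, and adjusted p = 0.610 with an estimated correlation); adjusted over the list alone the count was the same. Without control library 1 their median was 0.21 (adjusted p = 0.0768), with the length trend removed 0.05 (adjusted p = 0.181), with the GC trend removed 0.14 and with library size alone 1.10. The host median of 0.57 lay above the central range of random lists matched on length and expression (-1.17 to -0.17). SNHG17 rose by 2.21 ± 0.10 and EPB41L4A-AS1 by 1.59 ± 0.17, whereas SNHG16 fell with a log2 fold change of -0.75 ± 0.10. Box C/D snoRNAs, guides of RNA methylation, rose in 53 of 135 genes and fell in 10, with a median of 1.36 (adjusted p = 0.00495, and adjusted p = 0.650 with an estimated correlation). Adjusted over the list alone 47 rose and 9 fell. The median of 1.36 lay above the central range of random lists matched on length and expression (0.03 to 0.96). It was -0.04 with the length trend removed. With library size alone it was 1.88, though the list was then not called (camera adjusted p = 0.233). SNORD12C rose by 3.14 ± 0.27 and SNORD45B by 2.54 ± 0.30, while SNORD17 gave -1.13 ± 0.39. ZNF zinc-finger genes, most of them transcription regulators, rose in 157 of 454 and fell in 55, by a median of 0.35 (adjusted p = 0.00495, and adjusted p = 0.281 with an estimated correlation). Adjusted over the list alone 146 rose and 54 fell, and the median was -0.06 with the GC trend removed. ZNF789 rose by 2.45 ± 0.17 and ZNF767P, annotated as a pseudogene, by 2.42 ± 0.14.

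mtDNA-encoded RNAs fell as a group. All 13 mtDNA-encoded mRNAs fell, also when adjusted over the list alone, by a median log2 fold change of -2.79 (camera adjusted p = 4.13e-23; adjusted p = 0.281 with an estimated correlation). MT-CO1, a cytochrome c oxidase subunit, gave -2.58 ± 0.16, MT-CO2 -2.85 ± 0.12 and MT-ND1 -2.79 ± 0.19. All 23 mtDNA-encoded rRNAs and tRNAs fell, also adjusted over the list alone, with a median of -2.51 (adjusted p = 1.36e-06, and adjusted p = 0.186 with an estimated correlation). MT-RNR2, the large mitochondrial rRNA, gave -2.38 ± 0.19. The share of counts in mtDNA-encoded genes was 4.49% and 3.19% in the controls and 0.850% and 0.812% in the labelled libraries.

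Nuclear-encoded mRNAs for mitochondrial proteins fell as well. Subunits of oxidative phosphorylation (OXPHOS) fell in 72 of 79 genes and rose in 2, or 73 and 2 adjusted over the list alone, by a median of -1.40 (adjusted p = 7.92e-23; adjusted p = 0.281 with an estimated correlation). ATP5F1B, the catalytic ATP synthase subunit, fell from 578 ± 36.9 to 153 ± 15.2 CPM (log2 fold change -1.92 ± 0.11), and COX7C gave -1.99 ± 0.11. Mitochondrial ribosomal proteins fell in 69 of 82 genes and rose in 1 (70 and 1 adjusted over the list alone), by a median of -1.11 (adjusted p = 1.08e-13; adjusted p = 0.322 with an estimated correlation). MRPL51 gave -1.88 ± 0.14, and MRPS25 was the gene that rose, by 1.21 ± 0.10. TCA cycle and matrix enzymes fell in 53 of 71 and rose in 4 (53 and 5 adjusted over the list alone), by a median of -0.86 (adjusted p = 1.68e-11; adjusted p = 0.186 with an estimated correlation). The matrix chaperonin HSPD1 gave -1.81 ± 0.10. Import and outer-membrane proteins fell in 40 of 55 and rose in 3 (42 and 3 adjusted over the list alone), by a median of -0.97 (adjusted p = 5.94e-10; adjusted p = 0.240 with an estimated correlation). Their members TOMM20, an import receptor, and VDAC1, the outer-membrane channel, gave -1.81 ± 0.10 and -1.90 ± 0.10. SLC25 carriers of the inner membrane did not pass as a list, with 11 of 45 higher and 20 lower (12 and 20 adjusted over the list alone) and a median of -0.33 (adjusted p = 0.183).

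mRNAs of the cytosolic and secretory machinery also fell. Cytosolic ribosomal proteins fell in 77 of 79 genes and rose in 0, also adjusted over the list alone, by a median of -1.66 (adjusted p = 4.27e-45; adjusted p = 0.281 with an estimated correlation). By edgeR 0 of them rose, 0 rose in the authors' deposited table from DESeq2, and 1 of the 79 had a positive fold change. RPS4X gave -2.46 ± 0.14 and RPL15 -2.24 ± 0.11. Translation factors fell in 46 of 54 and rose in 2 (47 and 2 adjusted over the list alone), by a median of -1.02 (adjusted p = 1.21e-16; adjusted p = 0.186 with an estimated correlation), with EEF1A1, the elongation factor, at -2.03 ± 0.12. Glycolysis genes fell in 13 of 17 and rose in 1, also adjusted over the list alone, by a median of -1.39 (adjusted p = 1.98e-09; adjusted p = 0.281 with an estimated correlation). GAPDH fell from 1661 ± 79.2 to 372 ± 58.1 CPM (-2.16 ± 0.13) and LDHA gave -2.18 ± 0.10. Proteasome and CCT chaperonin genes fell in 40 of 42 (41 adjusted over the list alone), by a median of -1.40 (adjusted p = 1.22e-24; adjusted p = 0.187 with an estimated correlation), with CCT4 at -1.70 ± 0.10. Genes of folding, translocation and glycosylation in the endoplasmic reticulum (ER) fell in 69 of 79 and rose in 2, also adjusted over the list alone, by a median of -1.24 (adjusted p = 1.03e-26; adjusted p = 0.138 with an estimated correlation). The ER chaperone HSPA5 gave -2.04 ± 0.11 and the retrieval receptor KDELR1 -2.27 ± 0.10. Lysosomal hydrolases fell in 26 of 44 and rose in 8 (27 and 8 adjusted over the list alone), by a median of -0.73 (adjusted p = 0.00133; adjusted p = 0.281 with an estimated correlation). ACTB, cytoplasmic actin, fell from 2092 ± 54.2 to 511 ± 92.6 CPM (-2.03 ± 0.14).

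Replication-dependent histones, whose mRNAs lack a poly(A) tail, fell in 38 of 43 genes (39 adjusted over the list alone), by a median of -1.83 (adjusted p = 6.87e-11; adjusted p = 0.462 with an estimated correlation). Immediate-early and heat-shock genes fell in 21 of 32 (22 adjusted over the list alone), by a median of -1.22 (adjusted p = 1.61e-05; adjusted p = 0.281 with an estimated correlation), with the chaperone HSPA8 at -1.85 ± 0.11. The other lists did not pass. Cell-surface receptors and adhesion proteins had 19 of 171 higher and 60 lower (19 and 59 adjusted over the list alone; median -0.16, adjusted p = 0.225), and SLC carriers outside SLC25 had 49 of 218 higher and 76 lower, also adjusted over the list alone (median 0.02, adjusted p = 0.410). Spliceosomal snRNAs had 12 of 33 lower (11 adjusted over the list alone) and a median of -1.19 (adjusted p = 0.107, but 0.000339, 0.0356 and 0.0116 without control library 1, control library 3 or labelled library 1, 0.00228 with library size alone and 0.00185 with the length trend removed). Box H/ACA snoRNAs, guides of pseudouridylation, had 20 of 118 higher and 11 lower (12 and 9 adjusted over the list alone; median 0.52, adjusted p = 0.192, but 0.00837 and a median of 1.20 without control library 3, 0.0303 and 0.13 with the GC trend removed, and a median of 0.04 with the camera direction turned down without control library 1; the median was -0.82 with the length trend removed). The scaRNAs had 2 of 23 higher and 3 lower, or 1 and 3 adjusted over the list alone (median -0.12, adjusted p = 0.980). Their median was -0.44 without control library 1 and 0.53 without control library 3. Cytosolic non-coding RNAs had 5 of 9 lower, also adjusted over the list alone (median -1.61, adjusted p = 0.0936, but 4.1e-09, 0.0428 and 0.0267 without those libraries, with medians of -2.35, -0.51 and -2.02, 0.00967 with library size alone and 0.00208 with the length trend removed), among them the Y RNA RNY3 at -4.07 ± 0.47. Of 6 other nuclear non-coding RNAs 2 fell, also adjusted over the list alone (median -1.16, adjusted p = 0.286, but 0.00632 with the length trend removed). Both that fell are identifiers of RMRP with the same values, -1.79 ± 0.36. The list median was -0.55 without control library 3 and -1.60 without labelled library 1. RN7SK, which holds the elongation factor P-TEFb, was at -0.53 ± 0.26 (adjusted p = 0.111). CLK kinases and SR proteins had 12 of 31 higher and 12 lower (13 and 12 adjusted over the list alone; median 0.11, adjusted p = 0.570, but 0.0109 and a median of 0.63 with library size alone), with the splicing factor RBM5 at 1.59 ± 0.10 and SRSF9 at -1.28 ± 0.09. Markers of other cell types had 1 of 6 higher and 1 lower, or 0 and 1 adjusted over the list alone (median -0.04, adjusted p = 0.862). Their median was 0.03 without control library 1 and -1.86 without labelled library 3. With library size alone the medians of the SLC25, surface, scaRNA and other-cell-type lists turned positive, at 0.19, 0.36, 0.40 and 0.48, and that of SLC carriers outside SLC25 was 0.54. The falls were smaller under that scaling, which raised the median of all genes to 0.66: lysosomal hydrolases were at -0.21, TCA and matrix enzymes at -0.34, import genes at -0.45, translation factors at -0.50, mitochondrial ribosomal proteins at -0.59, immediate-early and heat-shock genes at -0.70, ER genes at -0.73, glycolysis at -0.87, and OXPHOS and proteasome genes at -0.88. ZNF genes were at 0.87. All these lists stayed past the test. With the length trend removed histones were at -3.16 and mtDNA-encoded rRNAs and tRNAs at -3.91, and with the GC trend removed lysosomal hydrolases were at -1.22 and box C/D snoRNAs at 0.87.

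In the labelled libraries of the outer mitochondrial membrane 20 genes were higher, among them 4 of the ER list, and mtDNA-encoded RNAs were lower. AASS, a mitochondrial enzyme of lysine breakdown, rose from 42.5 ± 10.0 to 525 ± 52.4 CPM (SD, n = 2 each), a log2 fold change of 3.63 ± 0.26 (SE). CPS1, the first enzyme of the urea cycle, rose from 46.6 ± 16.5 to 404 ± 20.8 CPM (3.12 ± 0.30, adjusted p = 0.0218). Calnexin, CANX, an ER chaperone, rose from 1350 ± 88.3 to 4751 ± 1150 CPM (1.82 ± 0.20, adjusted p = 0.0316). MT-ND5, a complex I subunit, fell from 4014 ± 2248 to 668 ± 24.1 CPM (-2.59 ± 0.36, adjusted p = 0.0457).

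Of 14438 genes tested, 20 rose and 8 fell at an adjusted p under 0.05, against 857 and 667 at an unadjusted p under 0.05. The authors' deposited table, from DESeq2, called 1000 higher and 873 lower, among them all 28 genes called here. The count moved with other choices: 321 and 145 without a filter on low counts, 305 and 160 with a group mean of at least 10 counts, 48 and 16 with library size alone, 21 and 18 with the GC trend removed, and 2 and 0 with the length trend removed. Without control library 3 it was 335 and 77, without control library 4 128 and 76, without labelled library 2 169 and 107, and without labelled library 3 203 and 279. All 20 higher genes were called in each of these 4 fits, and all 8 lower ones except 1, MT-ND5, without labelled library 3.

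The 6 highest named genes were AASS (ENSG00000008311, chromosome 7 from 122075647 to 122144280), CPS1 (ENSG00000021826, chromosome 2 from 210477682 to 210679107), PDPR, TMTC3, GPC4 and LMAN1. PDPR, a regulator of pyruvate dehydrogenase phosphatase on chromosome 16 from 70113626 to 70162537, rose by 2.70 ± 0.25 (adjusted p = 0.0218). TMTC3, an ER membrane protein on chromosome 12 from 88142296 to 88199887, rose by 2.66 ± 0.27. GPC4, a cell-surface glypican, rose from 26.5 ± 2.65 to 142 ± 16.5 CPM (2.42 ± 0.32). LMAN1, a cargo receptor between the ER and the Golgi, rose by 2.14 ± 0.22 from 107 ± 13.1 to 470 ± 33.4 CPM. Genes named by the rule for lists and past the test were ALDH18A1, a mitochondrial enzyme of proline synthesis (1.92 ± 0.22), and SPCS3, a signal peptidase subunit (1.92 ± 0.19), besides CANX (1.82 ± 0.20). The other 11 higher genes lay outside the naming rule and were chosen after their values were seen. They include LARS2 and IARS2, mitochondrial tRNA synthetases, at 1.92 ± 0.23 and 1.70 ± 0.20. CERS6, a ceramide synthase, gave 2.11 ± 0.27, PIGK, a GPI transamidase subunit, 2.09 ± 0.27, and ERLIN2, of the ER membrane, 2.01 ± 0.25. The desmosomal cadherin DSC3 gave 2.04 ± 0.26, carboxypeptidase D (CPD) 1.96 ± 0.24, the ER lumen protein CALU 1.84 ± 0.20 and the nuclear envelope protein NEMP1 1.63 ± 0.23. STT3B, of the oligosaccharyltransferase, gave 1.53 ± 0.20 and SCD, an ER desaturase, 1.36 ± 0.18.

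**Figure D2:**
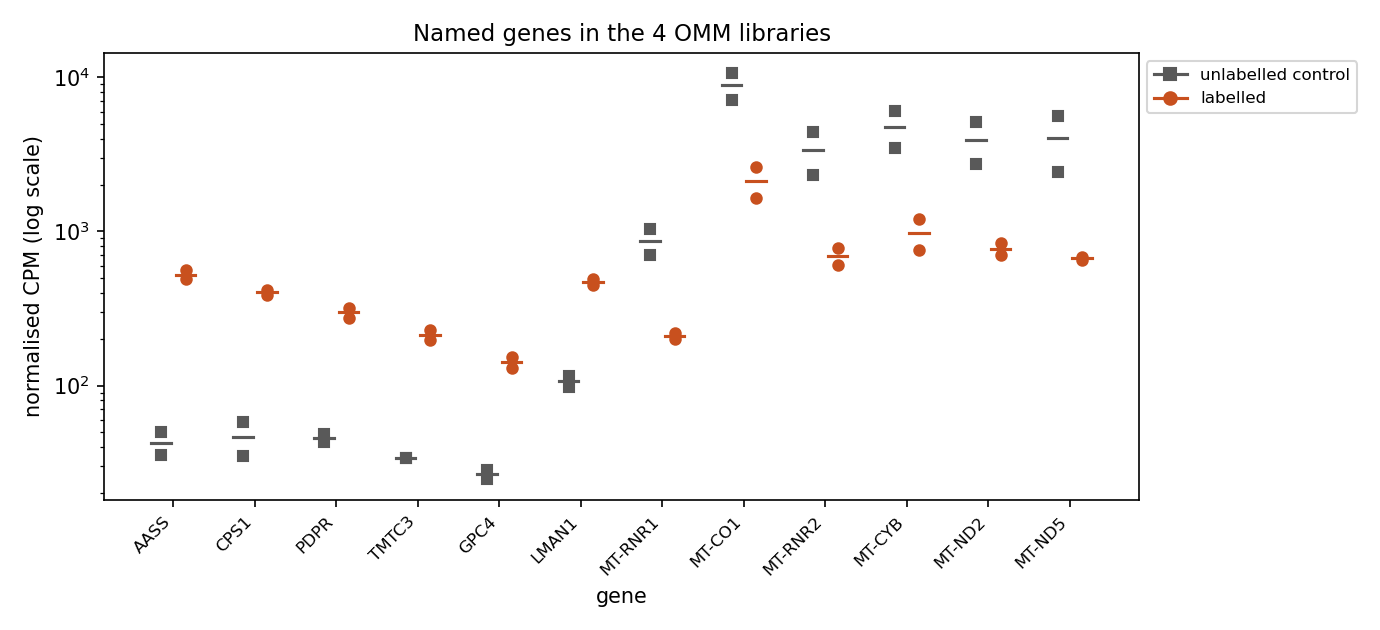
Normalised CPM (log axis) of the 6 highest and 6 lowest named genes in each of the 4 OMM libraries. Squares are unlabelled controls, circles labelled libraries, and lines the mean of 2 libraries; AASS lies at 525 against 42.5 CPM and MT-ND5 at 668 against 4014 CPM.

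The 8 genes that fell were 7 mtDNA-encoded RNAs and RPL36. MT-ND2, MT-CYB and MT-CO1 gave -2.35 ± 0.29, -2.28 ± 0.32 and -2.06 ± 0.27, the rRNAs MT-RNR2 and MT-RNR1 -2.28 ± 0.31 and -2.06 ± 0.24, MT-CO2 -1.91 ± 0.22, and RPL36, a cytosolic ribosomal protein, -1.49 ± 0.19. Of 13 mtDNA-encoded mRNAs, 5 fell, or all 13 adjusted over the list alone, with a median of -2.13 (camera adjusted p = 1.74e-41; adjusted p = 0.177 with an estimated correlation). MT-ND1 was at -2.13 ± 0.33 (adjusted p = 0.0552). Of 14 mtDNA-encoded rRNAs and tRNAs 2 fell, or 5 adjusted over the list alone, with a median of -3.01 (adjusted p = 2.45e-11; adjusted p = 0.193 with an estimated correlation). With 1 library left out this list stayed lower, but its median ran from -2.38 to -9.15, fitted values that rest on members at or near 0 counts and give no reliable size. The mtDNA-encoded share of counts was 7.19% and 4.29% in the controls and 1.17% and 1.65% in the labelled libraries.

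Lists of secreted and membrane proteins were higher at OMM. ER folding, translocation and glycosylation genes rose in 4 of 79, or in 27 with 1 lower adjusted over the list alone, with a median of 0.47 (adjusted p = 2.25e-13; adjusted p = 0.156 with an estimated correlation). The 4 were CANX, LMAN1, SPCS3 and STT3B, and their overlap with the 20 higher genes had an adjusted p of 8.66e-05 by Fisher's exact test. That test treats genes as independent and does not allow for how easily a gene of given abundance could be called. The ER chaperone HSPA5 was at 0.79 ± 0.24 (adjusted p = 0.281). Cell-surface receptors and adhesion proteins had 0 of 158 past the test, or 15 higher adjusted over the list alone, and 37 of 165 higher and 1 lower in the authors' deposited table; their median was 0.62 (adjusted p = 4.4e-08; adjusted p = 0.156 with an estimated correlation). ITGAV, an integrin, and TFRC, the transferrin receptor, were at 1.82 ± 0.31 and 1.49 ± 0.26. SLC carriers outside SLC25 had 0 of 185, or 3 higher adjusted over the list alone, with 44 of 190 higher and 6 lower in the authors' deposited table and a median of 0.47 (adjusted p = 1.07e-06; adjusted p = 0.156 with an estimated correlation). SLC16A1, a lactate carrier, was at 1.46 ± 0.23. Lysosomal hydrolases had 0 of 44, or 6 higher adjusted over the list alone, with 12 of 44 higher in the authors' deposited table and a median of 0.53 (adjusted p = 3.28e-07; adjusted p = 0.254 with an estimated correlation). LIPA, the acid lipase, was at 1.55 ± 0.22 (adjusted p = 0.0511). The lysosomal median was 0.30 without labelled library 2, and the cell-surface median 0.95 without control library 4 and 0.36 with the length trend removed.

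Several lists of cytosolic and nuclear-encoded mitochondrial mRNAs were lower, whereas the TCA and matrix list and the SLC25 list did not pass. Cytosolic ribosomal proteins fell in 1 of 79 genes, or in 65 adjusted over the list alone, with a median of -0.67 (adjusted p = 2.7e-38; adjusted p = 0.184 with an estimated correlation). RPS4X was at -0.74 ± 0.17 and RPL41 at -1.24 ± 0.20. OXPHOS subunits had 0 of 79 past the test, or 18 lower adjusted over the list alone, with 35 of 79 lower in the authors' deposited table and a median of -0.62 (adjusted p = 6.66e-20; adjusted p = 0.156 with an estimated correlation). ATP5ME, a small ATP synthase subunit, was at -1.85 ± 0.29 (adjusted p = 0.0552) and ATP5F1B at -0.10 ± 0.22. Mitochondrial ribosomal proteins had 0 of 82, and 0 adjusted over the list alone, with 17 of 82 lower in the authors' deposited table and a median of -0.44 (adjusted p = 2.11e-07; adjusted p = 0.156 with an estimated correlation). Proteasome and CCT genes had 0 of 42, and 0 adjusted over the list alone, with 12 of 42 lower in the authors' deposited table and a median of -0.40 (adjusted p = 3.52e-07; adjusted p = 0.193 with an estimated correlation). Import and outer-membrane proteins had 0 of 54, or 1 higher and 2 lower adjusted over the list alone, with a median of -0.26 (adjusted p = 0.0179; adjusted p = 0.193 with an estimated correlation); the adjusted p was 0.0670 without control library 3, 0.0782 without control library 4 and 0.498 without labelled library 3. TOMM40, the import channel, was at -1.24 ± 0.23 (adjusted p = 0.107), TOMM20 at 0.51 ± 0.18 and AKAP1, an outer-membrane anchor protein, at 1.00 ± 0.22. With the length trend removed the medians of the mitochondrial ribosomal protein and proteasome lists were -0.07 and -0.17 and these lists and the import list were no longer called. Ribosomal protein and OXPHOS medians were then -0.30 and -0.28 and still called. Nor were the snoRNA hosts and box C/D snoRNAs below, at an adjusted p of 0.0555 and 0.0586.

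Non-coding hosts of snoRNAs were lower, with 0 of 25 past the test, or 1 lower adjusted over the list alone, and a median of -0.80 (adjusted p = 0.000237; adjusted p = 0.177 with an estimated correlation). CLK kinases and SR proteins had 0 of 31, and 0 adjusted over the list alone, with a median of -0.28 (adjusted p = 0.00185, and adjusted p = 0.414 with an estimated correlation; 0.0591 without control library 3). Box C/D snoRNAs had 0 of 34, and 0 adjusted over the list alone, with 12 members at 0 counts in a group and a median of -1.63 (adjusted p = 0.00541; adjusted p = 0.302 with an estimated correlation; 0.169 without labelled library 2). With 1 library left out its fitted median ran from -0.60 to -8.65, so its size is not known. Lists not past the test were TCA cycle and matrix enzymes (1 of 71 higher, also adjusted over the list alone; median -0.06, adjusted p = 0.585), SLC25 carriers (39 genes, median -0.01, adjusted p = 0.990), translation factors (52 genes, median -0.27, adjusted p = 0.0642) and glycolysis (17 genes, median -0.21, adjusted p = 0.0528). So were nuclear long non-coding RNAs (27 genes, median -0.44, or 0.20 without control library 3 and -1.01 without labelled library 3, adjusted p = 0.449), box H/ACA snoRNAs (17 genes, adjusted p = 0.0603), histones (11 genes, adjusted p = 0.978), ZNF genes (415 genes, median 0.00, adjusted p = 0.990), and immediate-early and heat-shock genes (29 genes, median -0.04, adjusted p = 0.588). In these 8 lists 0 genes passed, also adjusted over the list alone. Glycolysis had an adjusted p of 0.00583 without control library 3 and 0.00393 without labelled library 2, and translation factors 0.0120 without labelled library 2 and 0.0371 with the GC trend removed. Box H/ACA snoRNAs had 6.07e-07 without control library 4, 0.00616 without labelled library 2, 0.0346 with library size alone and 0.0265 with the GC trend removed. ACTB, GAPDH, NEAT1 and MALAT1 were at -0.10 ± 0.18, -0.58 ± 0.16, -0.67 ± 0.67 and -1.16 ± 0.71, and none passed; the last 2 were positive without control library 3, at 0.14 and 0.20.

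**Figure D3:**
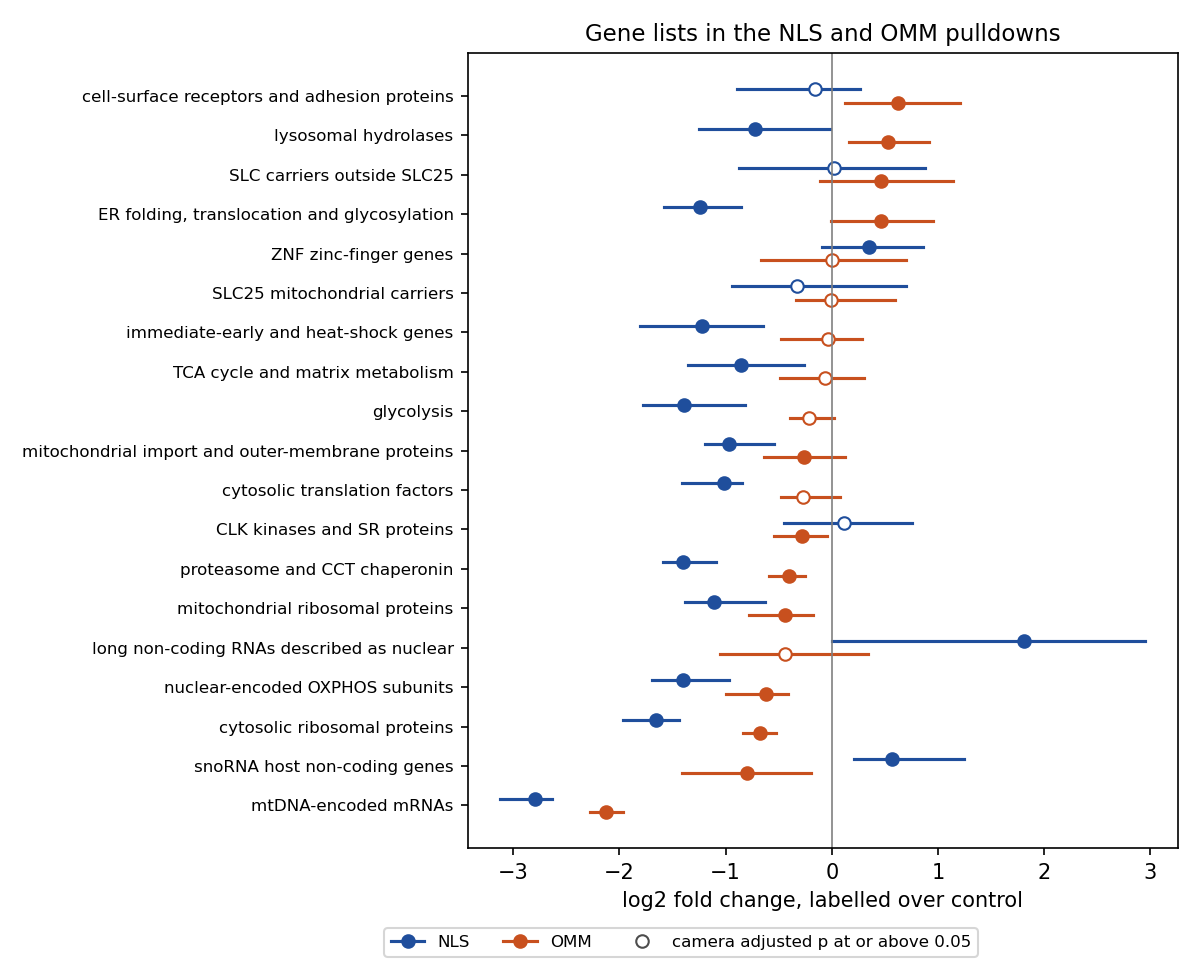
Median log2 fold change of labelled over control (points) with quartiles (lines) for gene lists at NLS and OMM; open points have a camera adjusted p at or above 0.05. ER genes lie at -1.24 at NLS and 0.47 at OMM, and mtDNA-encoded mRNAs at -2.79 and -2.13.

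The labelling effects at NLS and OMM were then compared directly, by the difference of their log2 fold changes (NLS minus OMM). This also holds the difference between kits. The joint fit pools the spread of both sites, so errors can be smaller than at OMM alone. For TMTC3 the error was 0.24 for the difference and 0.27 at OMM. Errors and adjusted p of differences that rest on OMM may therefore be too small. NEAT1 was higher at NLS by 4.53 ± 0.78 (SE, adjusted p = 0.0212) and PVT1 by 2.84 ± 0.50 (adjusted p = 0.0223). CPS1, TMTC3 and GPC4 were lower at NLS, with differences of -4.16 ± 0.40, -4.05 ± 0.24 and -4.02 ± 0.31 (adjusted p = 0.00496, 0.00277 and 0.00319). Housekeeping mRNAs were lower at NLS too, with HSPA5 at -2.86 ± 0.33 (adjusted p = 0.00715), ACTB at -1.96 ± 0.24, ATP5F1B at -1.84 ± 0.29 and GAPDH at -1.60 ± 0.18. MALAT1 at 3.46 ± 0.82 (adjusted p = 0.0540), RN7SK at -1.12 ± 1.68 (adjusted p = 0.928), MT-CO1 at -0.53 ± 0.40 (adjusted p = 0.548) and MT-ND1 at -0.68 ± 0.51 (adjusted p = 0.544) did not pass.

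Of 23178 genes tested, 326 had a higher and 1561 a lower effect at NLS; 125 of the 326 and 22 of the 1561 rested on at most 3 counts in some group. All 20 genes that rose at OMM passed this test with a lower effect at NLS. They were chosen on the same OMM values that enter the difference, so a lower effect was partly built in. At NLS 18 of them fell, against 5508 of all 13856 protein-coding genes tested there. AASS and PDPR were the exceptions at NLS, at 0.21 ± 0.12 and 0.05 ± 0.11. Of the 8 genes that fell at OMM, all fell at NLS and 0 passed the test of the difference by edgeR. Across the 14243 genes tested in both, which are not independent replicates, fold changes at the 2 sites had a Pearson correlation of -0.061 and a Spearman correlation of -0.026. The median difference of all genes was 0.11 under TMM; with size factors it was 0.52, with 372 higher and 626 lower, and with library size alone 0.57, with 381 and 584. Without NLS control library 1 or 3 edgeR called 0 genes in either direction, against 765 and 2578, or 877 and 2507, at an unadjusted p under 0.05; DESeq2 on all libraries called 2290 and 2030. Without NLS labelled library 1 or 3 it called 28 and 445, or 15 and 290. Without OMM control library 3 it called 836 and 2748, without control library 4 1053 and 1737, without labelled library 2 671 and 1769 and without labelled library 3 1454 and 2254.

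By lists, ER genes had the smallest p, with 49 of 79 lower at NLS, or 56 adjusted over the list alone, and a median difference of -1.65 (camera adjusted p = 4.58e-24; adjusted p = 0.0696 with an estimated correlation). Cytosolic ribosomal proteins were lower in 40 of 79, or 60 with 1 higher adjusted over the list alone, by a median of -1.03 (adjusted p = 3.11e-21; adjusted p = 0.233 with an estimated correlation). Nuclear long non-coding RNAs were higher in 9 of 32 and lower in 1, or 11 and 1 adjusted over the list alone, by a median of 2.08 (adjusted p = 4.39e-06; adjusted p = 0.119 with an estimated correlation), or 0.45 without OMM control library 3. mtDNA-encoded mRNAs had 0 of 13 past the test, also adjusted over the list alone, with a median of -0.74 (adjusted p = 0.0284; adjusted p = 0.661 with an estimated correlation). Their adjusted p was 0.229 without NLS control library 1, 0.0686 without NLS labelled library 3, 0.226 without OMM control library 4 and 0.197 without OMM labelled library 3.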

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

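The results below were singled out because the labelling effect at NLS differed from that at OMM by the interaction test of edgeR. No test was chosen here after the values were seen. Differences are NLS minus OMM on the log2 scale, and kit and RNA selection differed with the compartment. The effect was higher at NLS for 326 genes and lower for 1561.

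Among named genes the difference was 4.53 ± 0.78 (SE) for NEAT1 and 2.84 ± 0.50 for PVT1. It was -1.60 ± 0.18 for GAPDH, -1.84 ± 0.29 for ATP5F1B, -1.96 ± 0.24 for ACTB and -2.86 ± 0.33 for HSPA5. Of genes that rose at OMM it was -2.68 ± 0.22 for PDPR, -3.06 ± 0.23 for LMAN1, -3.43 ± 0.29 for AASS, -4.02 ± 0.31 for GPC4, -4.05 ± 0.24 for TMTC3 and -4.16 ± 0.40 for CPS1.

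For 7 genes a group held at most 3 counts, so counts are given in place of folds, controls before labelled libraries. KCNQ1OT1 (adjusted p = 0.0461) had 911, 1153, 12305 and 9584 at NLS and 229, 0, 0 and 1 at OMM. L3HYPDH (adjusted p = 0.00472) had 209, 196, 603 and 469, then 268, 762, 2 and 1. The mitochondrial tRNA MT-TF (adjusted p = 0.00828) had 1324, 582, 159 and 130, then 631, 731, 0 and 0. FIRRE (adjusted p = 0.00472), a nuclear non-coding RNA, had 761, 819, 1470 and 1326, then 113, 269, 1 and 0. SNORA73B (adjusted p = 0.0280) had 1506, 4319, 757 and 491, then 106, 133, 0 and 0. The kinase gene ULK4 (adjusted p = 0.0241) had 292, 252, 697 and 586, then 0, 1, 115 and 96. The histone gene H3C10 (adjusted p = 0.0205) had 1147, 1717, 348 and 136, then 0, 0, 74 and 257.

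Lists with a lower effect at NLS follow, with the camera adjusted p and the adjusted p with an estimated correlation in brackets. ER genes were at -1.65 (4.58e-24; 0.0696), proteasome and CCT genes at -1.08 (2.93e-12; 0.112), with 17 of 42 lower, or 31 adjusted over the list alone, and cytosolic ribosomal proteins at -1.03 (3.11e-21; 0.233). Glycolysis was at -1.24 (1.23e-06; 0.241), with 11 of 17 lower, or 12 adjusted over the list alone. Immediate-early and heat-shock genes were at -1.30 (0.00791; 0.112), with 5 of 34 lower, or 6 adjusted over the list alone. Cell-surface genes were at -1.06 (0.00115; 0.112), with 22 of 193 lower, or 26 with 1 higher adjusted over the list alone. Lysosomal hydrolases were at -1.03 (3.96e-07; 0.162), with 11 of 44 lower, or 15 adjusted over the list alone, and translation factors at -0.92 (3.23e-09; 0.112), with 21 of 55 lower, or 29 with 2 higher adjusted over the list alone. TCA and matrix enzymes were at -0.83 (1.02e-07; 0.112), with 18 of 71 lower, or 29 with 1 higher adjusted over the list alone. OXPHOS subunits were at -0.77 (3.21e-06; 0.262), with 11 of 79 lower and 1 higher, or 26 and 2 adjusted over the list alone. mtDNA-encoded mRNAs were at -0.74 (0.0284; 0.661), and their adjusted p was 0.111 with library size alone. Import and outer-membrane genes were at -0.72 (0.000513; 0.160), with 10 of 55 lower and 2 higher, or 15 and 2 adjusted over the list alone.

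Mitochondrial ribosomal proteins were at -0.66 (camera adjusted p = 5.74e-05; adjusted p = 0.199 with an estimated correlation; 0.0579 with library size alone), with 7 of 82 lower and 1 higher, or 13 and 1 adjusted over the list alone. SLC carriers outside SLC25 were at -0.63 (0.00290; 0.0696 with an estimated correlation), with 30 of 231 lower and 3 higher, or 46 and 5 adjusted over the list alone. Lists with a higher effect at NLS were nuclear long non-coding RNAs at 2.08 (4.39e-06; 0.119 with an estimated correlation) and snoRNA hosts at 1.44 (3.39e-07; 0.112), with 5 of 29 higher and 1 lower, or 11 and 1 adjusted over the list alone. Fitted medians were 1.71 for box C/D snoRNAs (0.000490; 0.282), with 6 of 142 higher and 1 lower and 0 adjusted over the list alone, and 1.39 for box H/ACA snoRNAs (0.000779; 0.422), with 4 of 125 higher and 0 adjusted over the list alone; 118 and 111 of their members had a group at 0 counts. mtDNA-encoded rRNAs and tRNAs were at 1.21 (0.00358; 0.385), with 2 of 24 higher, also adjusted over the list alone, and 12 members with a group at 0. ZNF genes were at 0.30 (0.0103; 0.317), with 13 of 463 higher and 8 lower, or 5 and 4 adjusted over the list alone. Without OMM control library 3 these last 2 medians turned to -1.11 and -0.13. CLK kinases and SR proteins were at 0.19 (0.0227; 0.429), with 5 of 31 higher and 3 lower, or 13 and 8 adjusted over the list alone. With library size alone, which moved the median difference of all genes to 0.57, OXPHOS subunits were at -0.32, mitochondrial ribosomal proteins at -0.21, TCA enzymes at -0.37, import genes at -0.28, mtDNA-encoded mRNAs at -0.31, cell-surface genes at -0.61 and SLC carriers at -0.18. Lysosomal hydrolases were then at -0.58, cytosolic ribosomal proteins at -0.57, translation factors at -0.47, glycolysis at -0.77, proteasome genes at -0.61, immediate-early and heat-shock genes at -0.84, ZNF genes at 0.77 and CLK and SR genes at 0.63. Lists not past the test were SLC25 carriers (adjusted p = 0.0842), snRNAs (0.107), scaRNAs (0.165), other nuclear non-coding RNAs (0.274), cytosolic non-coding RNAs (0.714), histones (0.975) and markers of other cell types (0.893).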

How the results depend on the processing

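Removal of the length and GC trends, separate spreads per compartment and the block in the difference were chosen after the data were seen, the other settings before. A lone library left in a group is assumed to vary like the other groups. No named gene past the test turned its direction. Of list medians past the test, those of box C/D snoRNAs at NLS (length trend removed, -0.04), ZNF genes at NLS (GC trend removed, -0.06, camera still higher) and, for the difference without OMM control library 3, mtDNA-encoded rRNAs and tRNAs (-1.11) and ZNF genes (-0.13) did. The cause of changes in counts was not tested unless the setting itself gives it. Of all genes called at NLS, 6 were called in the opposite direction with library size alone, 5 with the length trend removed and 2 with the GC trend removed. The highest, lowest and anchor genes past the test at NLS stayed past it in each setting that kept them; the mtDNA-encoded ones have no value without mtDNA-encoded, ribosomal and small RNAs. In simulated counts 85% of 2-fold changes were recovered at NLS, 5% at OMM and 0% for the difference, among genes averaging at least 100 counts.

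At NLS 5999 genes were higher and 5945 lower. The counts were 9122 and 3351 with library size alone, and 2838 and 1707 tested against a log2 fold change of 1. With 1 library left out, 3077 to 8425 were higher and 4520 to 6953 lower. With the replicate number as a block they were 5075 and 5696; the correlation of deviations of same-numbered libraries was -0.022 over 2 pairs, so the numbers were not shown to pair the libraries. Under the block snRNAs and cytosolic non-coding RNAs were lower as lists (adjusted p = 0.0269 and 0.00778). Of lists, 4 were higher and 14 lower. With an estimated correlation the counts were 0 and 0, with fry 2 and 16, and with the length trend removed 2 and 17.

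At OMM 20 genes were higher and 8 lower. The counts were 48 and 16 with library size alone, 321 and 145 with no filter, 305 and 160 with a group mean of at least 10 counts, and 1000 and 873 with DESeq2. Tested against a log2 fold change of 1 they were 1 and 0 (209 and 136 at an unadjusted p under 0.05). Size factors gave 26 and 11. Without mtDNA-encoded, ribosomal and small RNAs, which removes most lower genes by construction, 19 and 1 were called. With the length trend removed 2 and 0 were called (474 and 314 at an unadjusted p under 0.05), and with the GC trend removed 21 and 18. With 1 library left out, 128 to 335 were higher and 76 to 279 lower. Of lists, 4 were higher and 10 lower; with an estimated correlation 0 and 0, with fry 0 and 0, and with the length trend removed 5 were lower. No paired analysis was possible because the OMM columns of the 2 arms share only the number 3.

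For that difference 326 genes were higher and 1561 lower. The counts were 372 and 626 with size factors, 381 and 584 with library size alone, 676 and 1997 with no filter, 360 and 959 with a group mean of at least 10 counts, and 2290 and 2030 with DESeq2. Tested against a log2 fold change of 1 they were 35 and 251, and with separate spreads 140 and 1725. With a replicate block on the NLS numbers alone they were 69 and 789, with 7 lists higher and 14 lower. With 1 library left out, 0 to 1454 were higher and 0 to 2748 lower; the 0 calls by edgeR arose without NLS control library 1 or 3, where 765 and 2578, or 877 and 2507, had an unadjusted p under 0.05. Of lists, 7 were higher and 14 lower; with an estimated correlation 0 and 0, with fry 2 and 9, and with 1 library left out 4 to 7 were higher.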

Other observations

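All tests and comparisons in this part were chosen after the patterns they concern were seen, and those on control counts, on snoRNAs with no host, on mitochondrial ribosomal proteins alone and on library size as the whole cause also after an earlier test of the same pattern. Outside the fixed lists, several gene classes held RNAs that rose at NLS, where 5999 of all 20858 genes rose. Of 476 tested genes annotated as sense intronic, 344 rose and 6 fell, with a median log2 fold change of 2.97. Long intergenic non-coding RNAs rose in 507 of 1071 and fell in 25 (median 1.88), and antisense RNAs rose in 538 of 1359 and fell in 36 (median 1.52). Processed pseudogenes rose in 586 of 1095 and fell in 145 (median 2.50), microRNA genes in 122 of 345 and fell in 31 (median 1.98). Protein-coding genes rose in 2686 of 13856 and fell in 5508 (median -0.26). These medians take genes with a group at 0 counts at the bound of 3 counts per library, and no enrichment test was run. Such genes numbered 66 of the 476 sense intronic and 33 of the 13856 protein-coding genes. The filter on low counts can keep a gene for its labelled libraries alone, so the rise of low-count classes may be partly selected. At OMM all 20 higher and 6 of the 8 lower genes were protein-coding.

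At OMM, lists of short mRNAs were lower and secretory lists higher, though no list passed with an estimated correlation (smallest adjusted p = 0.156) or with fry, and the median fold change of protein-coding genes went from -0.41 among the shortest transcripts (below 2173 nt) to 0.37 among the longest (above 6012 nt). Against random lists matched on length and expression, 3 of 3 short-mRNA lists (cytosolic ribosomal, OXPHOS and mitochondrial ribosomal) lay below the central 95%. Of secretory and membrane lists, 4 of 4 lay above it. With the length trend removed, cytosolic ribosomal and OXPHOS lists stayed lower, at -0.30 and -0.28. This argues against the length of the longest annotated transcript as the whole cause. By that measure the median length was 1857 nt in the cytosolic ribosomal list and 1582 nt in the OXPHOS list. The length of the RNA present was not known, so a bias from it stays open for the short-mRNA lists. By annotated length itself the bias stays open for mitochondrial ribosomal proteins, whose median of -0.44 lay just below the matched range (-0.42 to -0.14). Their median was -0.0717 with the trend removed (camera adjusted p = 0.134). It also stays open for the proteasome and import lists, whose calls ended too (adjusted p = 0.0555 and 0.505). With 1 library left out, 0 of 12 and 0 of 16 medians turned sign, which argues against 1 library setting the direction. A median that fell to near 0 would not be counted, so 1 library as the main cause is not excluded. No biological explanation was tested, and labelling itself stays open as untested.

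At NLS, mRNA and mtDNA lists were lower and the nuclear long non-coding RNA list higher. No list passed camera with an estimated correlation (smallest adjusted p = 0.138), a test of little power here, whereas 18 of 28 passed fry. Controls had over 2 times the counts of labelled libraries. The library size difference was tested by thinning the controls to 8785372 counts, with a bound of 0.1 on any move of 3 medians, set beforehand. That bound was missed: the nuclear list moved by 0.188, away from 0 (1.81 to 2.00), so an effect of depth on its size stays open. A second criterion, chosen after that result, asked whether depth could be the whole cause. The largest move toward 0 was 0.0639, with ribosomal proteins at -1.60 and mtDNA mRNAs at -2.73 after thinning. Thinning keeps the expected share of each gene, so these medians could hardly move toward 0. It concerns only the number of counts, and cannot decide on differences in RNA input or library complexity. For transcript length bias, 4 of 4 lists (cytosolic ribosomal, OXPHOS, proteasome, nuclear non-coding) lay outside the matched range. The TCA and matrix list lay inside it (-0.86 in -0.89 to -0.35) but was at -1.04 with the length trend removed. That trend cannot decide for mRNAs at NLS. It was fitted over all genes (Spearman correlation -0.223) and ran opposite to that among protein-coding genes (0.210). The bias stays open for that list. Lengths were those of the longest annotated transcripts, so a bias from the length of the RNA present stays open for the other lists too. Labelling itself also stays open, untested.

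Box C/D snoRNAs were called higher at NLS, and the rise might reflect reads from unspliced host introns. The camera call was lost with an estimated correlation (adjusted p = 0.650) and with library size alone (median 1.88, adjusted p = 0.233). It was also lost with the length trend removed (median -0.04, adjusted p = 0.708). Against random lists matched on length and expression, however, the box C/D list lay above the matched range (1.36 against 0.03 to 0.96). These length checks point different ways, so a bias from transcript length stays open for box C/D snoRNAs. The 45 inside introns had a median of 1.73 and 290 intronic copies of other small RNAs 2.86, a difference of -1.13 that met the criterion set before the test, but 106 of the copies had a group at 0 counts, so the filter on low counts favoured copies with high fold changes. Among genes with at least 10 counts in each control the difference was -1.07, with 22 snoRNAs and 11 copies (permutation p = 0.129), too few to decide. The 8 box C/D snoRNAs with no host gene had a median of -1.51 (quartiles -1.69 to 1.32; 2 rose and 4 fell), while 82 that overlap an exon of some host transcript had a median of 1.33 (32 rose and 4 fell). The bounds of these last 2 tests were made stricter after their values were seen, and the first bounds would have counted both in favour of host introns, which stay open, as does labelling itself, untested.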
